A study of Homo sapiens with 4 samples.

How the data were processed

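RNA was measured in TF-1 cells, a human erythroleukaemia line that depends on added cytokine and was grown here with IL-3 and serum. Per the labels' protocols, cells were transduced with a lentivirus carrying a short hairpin RNA against TRAF6 or a control vector, at a multiplicity of infection of 0.5 to 1, and cells positive for the GFP marker were sorted 2.5 days later. A single TRAF6 hairpin was used. The sources give the control in one place by the name of the vector backbone and in another as a vector with scrambled sequences, so an effect of carrying any hairpin is not excluded. Per the labels' protocols, 1 to 20 ng of total RNA was amplified and biotin-labelled with a whole-transcript kit before hybridisation. The labels give 2 control and 2 shTRAF6 samples, each on its own array. They do not say whether the replicates came from separate cultures. P-values for single genes therefore measure only the spread between these samples, which may be technical.

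The deposited values are log2 probe set intensities made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes the arrays to each other and summarises the probes of each set, and it compresses changes of dim probe sets. Its version and settings are not given in the sources used here. The log2 scale was read from the values, which lay between 2.80 and 14.2 on the 4 arrays. The deposited table holds 33297 probe sets, and the array medians lay between 6.64 and 6.74. The number of arrays limits the precision here, and no read depth applies.

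Probe sets were named from a platform annotation dated 2016. It lists 1 gene for 19460 probe sets, several for 1754 and none for 12083, and probe sets with several genes named no gene. The Entrez identifiers of 19429 of the 19460 were found in a RefSeq gene table on GRCh38.p14, and 0 symbols needed an update. That table served for names, gene classes and the order of neighbouring genes. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed.

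Each gene took the mean of the log2 values of the probe sets that name that gene alone, which gave 18417 genes, 769 of them with more than 1 probe set. No filter on dim probe sets and no further normalization were applied. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, shTRAF6 minus control, no covariate, 2 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A gene is said to have risen or fallen where its adjusted p passed that threshold. With 2 residual degrees of freedom, the spread of each gene rests largely on the value eBayes borrows from the other genes.

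Before the data were examined, 36 gene lists were fixed from textbook pathways, complexes and cell type markers, none of them taken from these samples. They were tested with camera at a preset correlation between genes of 0.01, two-sided and adjusted over the 36 lists. That preset treats genes as nearly independent, so these list p-values largely measure spread over genes, not between samples. An estimated correlation, fry and a rank form of camera were the alternatives. Counts of members are given over all genes tested and adjusted over the list alone. The rule for named genes was fixed at the same time. It takes TRAF6 and PSMA1, then the 12 largest changes in each direction among genes past the threshold whose groups do not overlap, then up to 4 members of each list by smallest p. Genes without an official symbol, small RNA genes and near-identical families were to be passed over among the largest changes. Which families and gene classes that meant was settled only after values had been seen, and in the top range it passed over the pseudogene NMRAL2P (log2 change 1.47).

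Alternatives fixed beforehand were the replicate number as a block, each array left out in turn, quantile normalization, centring on the array medians, leaving out genes under the 25th or 50th percentile of level, the brightest probe set per gene, other forms of eBayes, no moderation, every probe set tested, and other fold minimums. The single-probe-set fit, the robust fit over every probe set, the TRAF6 and PSMA1 values in the fits over probe sets, the snoRNA counts, the list counts by setting, the share of falls by scaling and the values of genes outside the naming rule were added after the data had been seen. The fit was tested on simulated values for this comparison over 18417 genes, 200 of them changed. It recovered 11% of the genes changed by 0.5 on the log2 scale and 92% of those changed by 1, and 0.962% of its calls were unchanged genes. A simulated list shifted by 0.25 passed with the preset correlation and had an adjusted p of 0.202 with an estimated one. The simulated genes were independent of each other, with spreads drawn from the distribution that eBayes fitted. The model therefore held by construction, and these results do not gauge errors among the calls in the real samples.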

Results

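Gene expression was profiled on whole-transcript arrays in TF-1 erythroleukaemia cells carrying a control vector (2 arrays) or a hairpin against TRAF6 (2 arrays), sorted for GFP 2.5 days after transduction. TRAF6 is a ubiquitin ligase that carries signals from Toll-like and IL-1 receptors to NF-kB. The comparison asked which transcripts differ when TRAF6 is knocked down, and the series title names PSMA1, a subunit of the 20S proteasome core, as a gene of interest. Median log2 intensities were 6.69 and 6.66 on the control arrays and 6.64 and 6.74 on the shTRAF6 arrays. Pearson's r over probe sets was 0.997 within control, 0.996 within shTRAF6 and 0.992 to 0.995 between the groups, across probe sets that are not independent replicates. The median absolute difference was 0.0973 within control, 0.128 within shTRAF6 and 0.120 to 0.165 between groups, and no arrays were duplicates.

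TRAF6 fell in the cells with the hairpin, and PSMA1 fell by more. TRAF6 was at 8.59 ± 0.122 (SD, n = 2) in control and 8.08 ± 0.164 (SD, n = 2) in shTRAF6, which is 1.42-fold lower (log2 change -0.51, SE 0.11, limma adjusted p = 0.0479). PSMA1 was at 11.51 ± 0.0288 (SD, n = 2) in control and 10.59 ± 0.186 (SD, n = 2) in shTRAF6, 1.88-fold lower (log2 change -0.91, SE 0.11, limma adjusted p = 0.00946). Both shTRAF6 arrays lay below both control arrays for each gene. In size of fall PSMA1 ranked 34 and TRAF6 196 of 18417 genes, and 184 genes that passed the test fell by more than TRAF6 (143 without control 1, 120 without control 2, 205 without shTRAF6 1 and 109 without shTRAF6 2). The TRAF6 call is marginal: its adjusted p was 0.0715 without control 1 (log2 change -0.59), 0.147 without control 2 (-0.42), 0.0967 without shTRAF6 1 (-0.39) and 0.0548 without shTRAF6 2 (-0.62). PSMA1 kept its call without any single array, and lost it without eBayes moderation (adjusted p = 0.332) and with every probe set tested (0.0792).

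**Figure D1:**
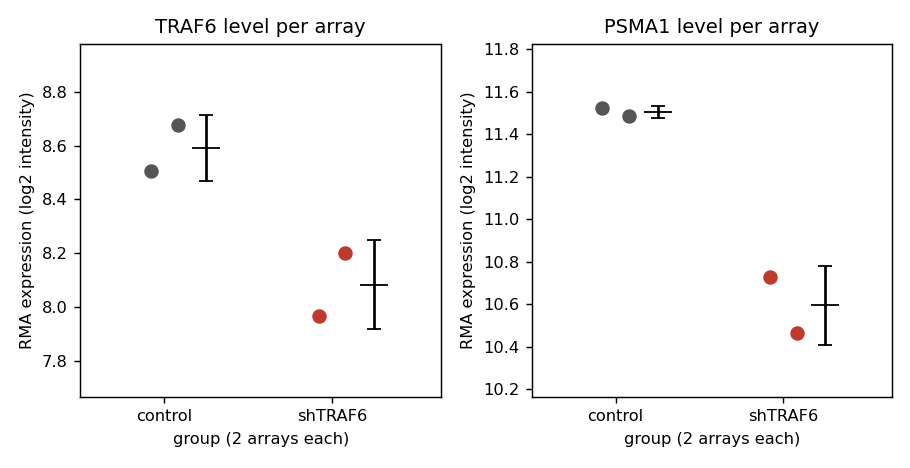
Expression of TRAF6 and PSMA1 on each array, as RMA log2 intensity, for control and shTRAF6 (2 arrays each, points), with the group mean and SD beside them. Both shTRAF6 points lie below both control points, with log2 changes of -0.51 for TRAF6 and -0.91 for PSMA1.

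Most other proteasome genes did not pass the test. Of 15 measured 20S core subunits, PSMA1 fell and PSMB5, a catalytic subunit, rose (log2 change 0.38, adjusted p = 0.0473), also when adjusted over the list alone (1 and 1). The 14 subunits other than PSMA1 had a median log2 change of 0.054 and ranged from -0.25 to 0.38, 9 above 0 and 5 below. Among these, PSMA3 was at -0.25 (adjusted p = 0.154) and PSMB7 at 0.21 (adjusted p = 0.234). Of 20 subunits of the 19S cap, which unfolds substrates for the core, UCHL5, a deubiquitinase, fell (-0.42), and 1 fell adjusted over the list alone, while 16 lay above 0 with a median of 0.13. Of 12 immunoproteasome and activator genes, PSMB8 fell (-0.48), and 1 fell adjusted over the list alone. By camera the adjusted p was 0.790 for the core (median 0.041, mean -0.0020, tested as up), 0.0868 for the cap (tested as up) and 0.215 for the immunoproteasome. The rise of PSMB5 was not called without any one of the 4 arrays. UCHL5 and PSMB8 were called without shTRAF6 1, and not without control 1, control 2 or shTRAF6 2.

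Across the transcriptome, 906 of 18417 genes passed the limma test, 629 higher and 277 lower in shTRAF6 (69.4% higher), and every one of them had groups that did not overlap. At least 1.5-fold changes made up 265 of the rises and 125 of the falls, and at least 2-fold changes 29 and 24. Over all genes, the groups did not overlap for 52.0%, against 33.3% by chance for 2 against 2. An unadjusted p under 0.05 was found for 3972 genes (921 expected by chance), and 421 of them also changed by 1.5-fold, 292 higher and 129 lower. The size of the count depends on the setting: it was 1 without moderation, 27 with every probe set tested and 2182 with centred arrays, and quantile normalization gave 844 higher and 784 lower (51.8% higher). So does the balance of directions: every probe set tested gave 9 higher and 18 lower. Leaving out an array moved the balance both ways. It was nearer to even without control 1 or shTRAF6 2, and leaned further towards rises without control 2 or shTRAF6 1. Which arrays were used also set the size of the count. It was 289 without control 1, 586 without control 2, 1099 without shTRAF6 1 and 250 without shTRAF6 2, of which 276, 478, 699 and 234 were among the 906.

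The largest rise was that of CROT, a carnitine acyltransferase of peroxisomes, from 5.94 ± 0.220 to 7.54 ± 0.0414 (SD, n = 2 each; 3.02-fold higher, log2 change 1.60, SE 0.12, limma adjusted p = 0.00256). CD80, a costimulatory ligand for T cells, rose by 1.49 and CFL2, an actin-severing cofilin, by 1.48 on the log2 scale. DDIT4, an inhibitor of mTORC1, rose by 1.36 (SE 0.17, adjusted p = 0.0118), CDKN1A, the cell cycle inhibitor p21, by 1.31 (SE 0.18, adjusted p = 0.0134), and DRAM1, a lysosomal membrane protein linked to autophagy, by 1.24 (SE 0.18, adjusted p = 0.0145). FAXDC2 rose by 1.37, EVI2B by 1.34, SLFN14 by 1.28, SEMA3C, a secreted semaphorin, by 1.25, the growth factor EGF by 1.21, and MAPRE3, which binds microtubule ends, by 1.19. Without shTRAF6 2, SLFN14 (log2 change 1.06, adjusted p = 0.0715), SEMA3C (1.12, 0.0552) and DRAM1 (1.11, 0.0526) did not pass.

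The largest fall was that of C1D, a nuclear cofactor of the RNA exosome read by 4 probe sets, from 9.39 ± 0.0127 to 7.66 ± 0.280 (SD, n = 2 each; 3.31-fold lower, log2 change -1.73, SE 0.13, limma adjusted p = 0.00256). PPP3CA, a catalytic subunit of the phosphatase calcineurin, fell by 1.55 (2.93-fold lower) and TMEM30A, a subunit of phospholipid flippases, by 1.52 (2.87-fold lower). OSBPL8, a lipid transfer protein, fell by 1.44, and the prion protein gene PRNP and CARNMT1 each fell by 1.38. The RNA-binding proteins QKI and RBMS1 fell by 1.33 and 1.27. HMGCS1, which makes HMG-CoA for cholesterol synthesis, fell by 1.25, the small GTPase RAP1B by 1.24, SKA2, a kinetochore protein, by 1.21 and the chemokine receptor CCR4 by 1.16. Each of these 12 falls passed the test without any single array.

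**Figure D2:**
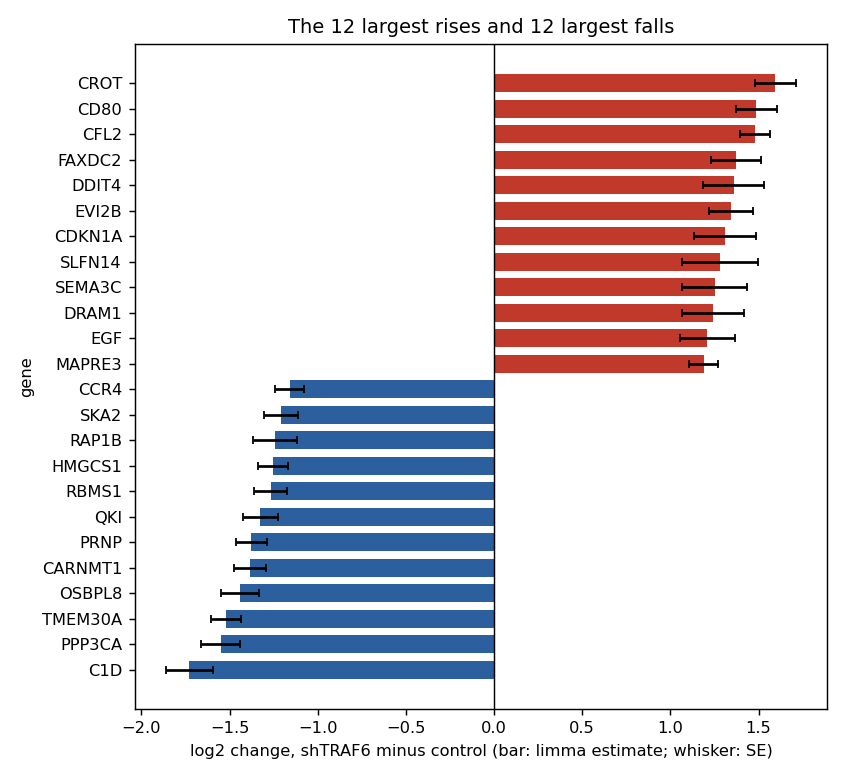
Log2 change (shTRAF6 minus control, 2 arrays each) of the 12 largest rises and 12 largest falls named by the fixed rule, with bars for the limma estimate and whiskers for its SE. Changes run from -1.73 for C1D to 1.60 for CROT.

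As a list, genes of the autophagy machinery lay higher by camera with the preset correlation, though not with an estimated one. Of 39 measured, 7 rose and 1 fell (18 and 2 adjusted over the list alone), the median log2 change was 0.24, and 33 lay above 0 (camera adjusted p = 4.70e-05; adjusted p = 0.964 with an estimated correlation). GABARAPL1, which decorates autophagosome membranes, rose by 1.13 (2.18-fold higher, SE 0.11, adjusted p = 0.00541), the cargo receptor NBR1 by 0.71, RB1CC1, a scaffold of the initiating kinase complex, by 0.72 and the protease ATG4D by 0.54. ATG3, an enzyme that attaches lipid to proteins of the GABARAP family and was named after its value was seen, fell by 0.49. Without control 1, control 2, shTRAF6 1 and shTRAF6 2, in that order, 2, 3, 7 and 1 genes rose, and ATG3 was called without shTRAF6 1 alone. The median was 0.15 without shTRAF6 2. Lysosomal genes did not move together: of 38, LIPA, the acid lipase, fell by 0.57 and the proton pump subunit ATP6V1A by 0.55, and 0 rose (3 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.752). Among those not past the test, CTSS was at 0.40 (adjusted p = 0.0509) and CTSD at 0.36 (adjusted p = 0.0612). In the same order of left-out arrays, 2, 0, 2 and 0 lysosomal genes fell and 0, 1, 0 and 0 rose. Quantile normalization gave 1 lysosomal rise and 3 falls, centred arrays 4 and 2, the replicate block 3 and 2, and an eBayes trend 6 and 4.

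Genes of the microRNA pathway had the highest median of the 36 lists. Of 13 measured, 12 lay above 0 with a median of 0.37, and 1 passed the test over all genes (8 rose and 0 fell adjusted over the list alone; camera adjusted p = 4.01e-04, adjusted p = 0.964 with an estimated correlation). TNRC6A, a scaffold of the silencing complex, rose by 1.13 (2.19-fold higher, SE 0.12, adjusted p = 0.00800). Not past the test were AGO4 at 0.44 (adjusted p = 0.0658), AGO1 at 0.49 (0.0997) and the nuclear exporter XPO5 at 0.30 (0.106). TNRC6A passed without any single array, and 1, 1, 7 and 1 genes of the list rose without control 1, control 2, shTRAF6 1 and shTRAF6 2 (medians 0.25 to 0.54). Quantile normalization gave 2 rises, centred arrays and the replicate block 6 each and an eBayes trend 7. AGO1 (0.70) and AGO4 (0.54) passed without shTRAF6 1, and AGO1 was at 0.28 without shTRAF6 2.

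Stress-response lists rose in part. Of 30 genes of the amino acid response, 6 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 5.99e-04; adjusted p = 0.964 with an estimated correlation). Beside DDIT4, CTH, which makes cysteine, rose by 0.64 and the amino acid transporter SLC7A5 by 0.53, while PSAT1, of serine synthesis, fell by 0.54. Of 21 NRF2 targets, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 5.99e-04; adjusted p = 0.964 with an estimated correlation). TXNRD1, thioredoxin reductase, rose by 0.47. AKR1C1 rose by 0.72, AKR1C2 by 0.76 and AKR1C3 by 0.57, which are uncertain because these genes are near-identical and probes may read several of them. Without control 1, control 2, shTRAF6 1 and shTRAF6 2, 2, 3, 10 and 1 amino acid response genes and 2, 3, 5 and 2 NRF2 targets rose, and PSAT1 was called without shTRAF6 1 alone. In the unfolded protein response, SEL1L, of the degradation of misfolded proteins, fell by 0.99, PPP1R15A rose by 0.89 and DDIT3, the transcription factor CHOP, by 0.73, so that 2 rose and 1 fell of 25 (3 and 1 adjusted over the list alone; camera adjusted p = 0.446). DNAJB9 was at 0.38 (adjusted p = 0.0558). Without control 1, 1 of that list rose, and without shTRAF6 2, 0 did. Limma called 0 of 18 heat shock genes (1 at an unadjusted p under 0.05; 0 adjusted over the list alone; camera adjusted p = 0.752), BAG3 being at 0.23.

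Cholesterol and lipid synthesis genes lay lower as a list by camera with the preset correlation, though not with an estimated one. Of 27 measured, 4 fell and 0 rose (7 and 2 adjusted over the list alone), with a median of -0.13 and 21 below 0 (camera adjusted p = 5.99e-04; adjusted p = 0.964 with an estimated correlation). Beside HMGCS1, ACLY, which makes cytosolic acetyl-CoA, fell by 1.04 (2.05-fold lower, SE 0.083, adjusted p = 0.00286), the sterol carrier STARD4 by 0.57 and DHCR7, a late enzyme of cholesterol synthesis, by 0.45. With the arrays left out in the same order, 3, 2, 3 and 2 of them fell and 0, 0, 1 and 0 rose. The falls numbered 9 with quantile normalization (1 rose) and 8 with centred arrays (2 rose). In glycolysis and hypoxia, PDK1, which inhibits pyruvate dehydrogenase, rose by 0.62 and BNIP3 by 0.48, and 0 of 32 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.126). KDM3A was at 0.52 (adjusted p = 0.0619). Without control 1 or shTRAF6 2, 0 of these rose, and without control 2 KDM3A passed (0.68). Quantile normalization gave 3 rises and 1 fall, and centred arrays 6 and 0. In oxidative phosphorylation NDUFA5, of complex I, fell by 0.43, the 1 call of 69 genes (0 adjusted over the list alone; camera adjusted p = 0.686), and it was lost without any one of the 4 arrays.

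Targets of NF-kB went both ways. Of 42, 2 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.752, tested as down with a median of 0.012 and a mean of 0.010). TNFAIP3, the feedback inhibitor A20, rose by 0.92 (1.89-fold higher) and the kinase MAP3K8 by 0.52. The cytokine IL1B fell by 0.49, PTGS2, the inducible cyclooxygenase, by 0.77 and, named after its value was seen, the chemokine CCL5 by 0.57. Of 38 genes of Toll-like and IL-1 receptor signalling, PELI1, a ubiquitin ligase, rose by 0.77, the receptor IL18R1 by 0.60 and the adaptor TIRAP by 0.55 (adjusted p = 0.0508 in the robust fit), and TRAF6 fell (5 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.138). TRAF6 was the 1 call among 6 TRAF genes (1 adjusted over the list alone; camera adjusted p = 0.704), with TRAF5 and TRAF3 both at 0.22 and TRAF4 at 0.16. Leaving out control 1, control 2, shTRAF6 1 and shTRAF6 2 in turn, 1, 3, 3 and 0 NF-kB targets rose and 1, 1, 2 and 2 fell, and 1, 5, 6 and 0 receptor signalling genes rose and 0 fell in each. Rises and falls of NF-kB targets were 3 and 6 with quantile normalization and 5 and 5 with centred arrays, and of receptor signalling genes 4 and 3 and 6 and 3. TRAF3 ranged from 0.14 to 0.31 and TRAF4 from 0.099 to 0.22 with 1 array left out.

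Other signalling lists held a few calls each. In the immediate early and ERK response, SPRED2, a feedback inhibitor of the pathway, fell by 0.78, and the transcription factors ETV4 and ETV5 by 0.63 and 0.65, and 0 of 33 rose (4 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.0576). KLF10 was at 0.58 (adjusted p = 0.0517). Of 18 IL-3 and STAT5 targets, the kinase PIM1 rose by 0.52, SOCS1, a cytokine feedback inhibitor, by 0.49 and the cytokine OSM by 0.54 (adjusted p = 0.0509 with the brightest probe set and 0.0520 in the robust fit), and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.110). CISH was at 0.30 (adjusted p = 0.106). Of 47 interferon-stimulated genes, 4 rose, among them IRF9 by 0.64, GBP2 by 0.84 and CMPK2 by 0.40, and USP18 fell by 0.64 (7 and 2 adjusted over the list alone; camera adjusted p = 0.228). GBP2 did not pass with the brightest probe set per gene (0.37, adjusted p = 0.0972), where 3 of the list rose, nor CMPK2 with quantile normalization (0.30, adjusted p = 0.0626). In the same order of left-out arrays, 1, 3, 3 and 2 ERK genes fell and 0, 0, 3 and 0 rose (KLF10 at 0.77 without shTRAF6 1 among them), 0, 1, 3 and 0 STAT5 targets rose, and 2, 5, 6 and 1 interferon-stimulated genes rose and 1, 0, 1 and 1 fell. Rises and falls of ERK genes were 2 and 5 with quantile normalization and 3 and 4 with centred arrays, and of interferon-stimulated genes 6 and 2 and 8 and 2.

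Apoptosis and p53 lists contained large single changes. XIAP, an inhibitor of caspases, fell by 1.15 (2.22-fold lower, SE 0.20, adjusted p = 0.0236), while PMAIP1 rose by 0.50, BNIP3L by 0.47 and CASP6 by 0.47, so that 5 rose and 1 fell of 33 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0973). Of 27 p53 targets, 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.670). Beside CDKN1A, GDF15 rose by 0.73 and SUSD6 by 0.60, and MDM2, the ligase that degrades p53, fell by 0.63. SESN1, named after its value was seen, fell by 0.51. Fits without control 1, control 2, shTRAF6 1 and shTRAF6 2 gave other counts: 0, 0, 2 and 0 apoptosis genes and 2, 5, 5 and 1 p53 targets rose, and 1, 1, 1 and 1 apoptosis genes and 1, 1, 2 and 1 p53 targets fell. SESN1 lost its call without control 1, control 2 or shTRAF6 2. With quantile normalization 5 apoptosis genes rose and 3 fell, with centred arrays 8 and 2, and with either 5 p53 targets rose and 3 fell.

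Cell cycle genes showed few calls. Of 45 replication and G1/S genes, E2F1 rose by 0.52 and UNG by 0.51 and DSCC1 fell by 0.64 (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.752), and TYMS was at -0.34 (adjusted p = 0.0610). Limma called 0 of 39 mitotic genes (9 at an unadjusted p under 0.05; 0 adjusted over the list alone; camera adjusted p = 0.752), HMMR being at -0.33 and ECT2 at 0.32. Replication-dependent histone genes had a median of -0.12 and lay below 0 for 43 of 50, though limma called 0 of them (5 at an unadjusted p under 0.05; 0 adjusted over the list alone). As a list they passed camera (adjusted p = 0.00420; adjusted p = 0.964 with an estimated correlation), but not without control 1 (adjusted p = 0.735, median -0.020) or shTRAF6 2 (0.839, -0.014). The median was -0.18 without control 2 and -0.19 without shTRAF6 1. H1-3 was at -0.34 and H4C8 at 0.30, values that are uncertain in so similar a family. Across the same left-out arrays, 0, 1, 2 and 0 replication genes rose and 1, 1, 1 and 0 fell, and 1 histone gene fell without control 2. Either rescaling gave 2 rises and 4 falls of replication genes and 1 fall each of mitotic and histone genes. An eBayes trend gave 2 rises and 3 falls of replication genes, 3 and 3 of mitotic genes and 1 and 6 of histone genes. With genes under the 50th percentile left out, 2 mitotic genes rose and 1 fell, and 1 histone gene rose and 1 fell.

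Cytosolic ribosomal proteins lay slightly higher, with a median of 0.071 and 51 of 56 above 0 (camera adjusted p = 0.0205; adjusted p = 0.964 with an estimated correlation). RPL22 rose by 0.62 (0 adjusted over the list alone), and RPL32 and RPL27A were both at 0.21. That list did not pass without control 2 (adjusted p = 0.210) or shTRAF6 1 (0.499), with centred arrays (0.0851) or with genes under the 50th percentile of level left out (0.268), and RPL22 was not called without control 1 or shTRAF6 2, with the brightest probe set (0.0508) or in the robust fit (0.0520). With quantile normalization the list passed at a median of 0.035. Limma called 0 of 30 ribosome biogenesis genes (4 at an unadjusted p under 0.05; 0 adjusted over the list alone; camera adjusted p = 0.752), RRS1 being at -0.50 (adjusted p = 0.0599), though 1 fell without control 1 (RRS1, -0.66) and with quantile normalization, 1 rose without control 2, and 1 rose and 1 fell with centred arrays.

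Erythroid genes, the lineage of TF-1, went both ways. Of 31, 3 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.284). The embryonic globin HBE1 rose by 0.68 and the minor adult globin HBD by 0.65, while the embryonic globin HBZ fell by 0.45 and carbonic anhydrase CA2 by 0.58. Globins are similar in sequence, so these values are uncertain. The platelet tubulin TUBB1 rose by 0.90 (SE 0.098, adjusted p = 0.00800), the 1 call of 16 megakaryocyte markers (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.752, tested as up with a median of -0.015 and a mean of 0.098), and THBS1 was at 0.74 (adjusted p = 0.0718). Without control 1, control 2, shTRAF6 1 and shTRAF6 2, 2, 2, 4 and 2 erythroid genes rose and 0, 0, 2 and 0 fell, and 1, 2, 3 and 1 megakaryocyte markers rose, THBS1 passing without control 2 (0.93) and shTRAF6 1 (1.00) and lying at 0.47 without shTRAF6 2. Quantile normalization gave 3 erythroid rises and 3 falls and 2 and 1 for megakaryocyte markers, and centred arrays 4 and 3 and 4 and 1. An eBayes trend gave 9 erythroid rises and 3 falls, and 3 and 1 for megakaryocyte markers.

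Markers of other blood cells were tested beside these. T and NK cell markers lay lower, 13 of 18 below 0 with a median of -0.060 (camera adjusted p = 0.0283; adjusted p = 0.964 with an estimated correlation). The T cell receptor subunits CD3D and CD3G fell by 0.71 and 0.38 (0 rose and 3 fell adjusted over the list alone), CD3D from a high level in control (10.24 ± 0.0610, SD, n = 2). Antigen presentation genes had 10 of 11 below 0 and a median of -0.18 (camera adjusted p = 0.0283; adjusted p = 0.964 with an estimated correlation), with 0 called by limma (4 at an unadjusted p under 0.05; 0 adjusted over the list alone) and CIITA, their master regulator, at -0.33. T and NK markers did not pass without control 1 (adjusted p = 0.164, median -0.037) or shTRAF6 2 (0.0661, -0.096) or with quantile normalization (0.0699), and their median was -0.027 without shTRAF6 1 and -0.32 with genes under the 50th percentile left out, where they passed, and antigen presentation did not without control 2 (adjusted p = 0.128, median -0.087) or shTRAF6 1 (0.110, -0.037) or with genes under the 50th percentile of level left out (0.180, -0.092), its median being -0.30 without shTRAF6 2. With genes under the 50th percentile left out, only 4 T and NK markers remained, 2 of them called falls, and 7 antigen presentation genes. CD3D passed with any one of the 4 arrays left out, and CD3G with none of them. Limma called 0 of 9 B cell, 17 granulocyte, 20 monocyte and macrophage, 9 mast cell, basophil and eosinophil, 13 stem and progenitor and 13 packaging line markers (1, 2, 2, 1, 3 and 0 at an unadjusted p under 0.05; 0 adjusted over each list alone). Their camera adjusted p-values were 0.110, 0.207, 0.483, 0.917, 0.917 and 0.752. CD34, a stem cell marker, was at -0.40 (adjusted p = 0.102; -0.55 to -0.25 with 1 array left out), and CIITA ranged from -0.45 to -0.20. Either rescaling called falls of 4 T and NK markers and 1 antigen presentation, 1 monocyte and 1 stem cell gene (centred arrays also 1 rise of a stem cell gene and falls of 1 B cell and 1 granulocyte marker). Median and test differed in sign for the mast cell list (0.037, tested as down) and the stem cell list (0.0074, tested as down), and the packaging list had a median of -0.026 with a mean of 0.0015.

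**Figure D3:**
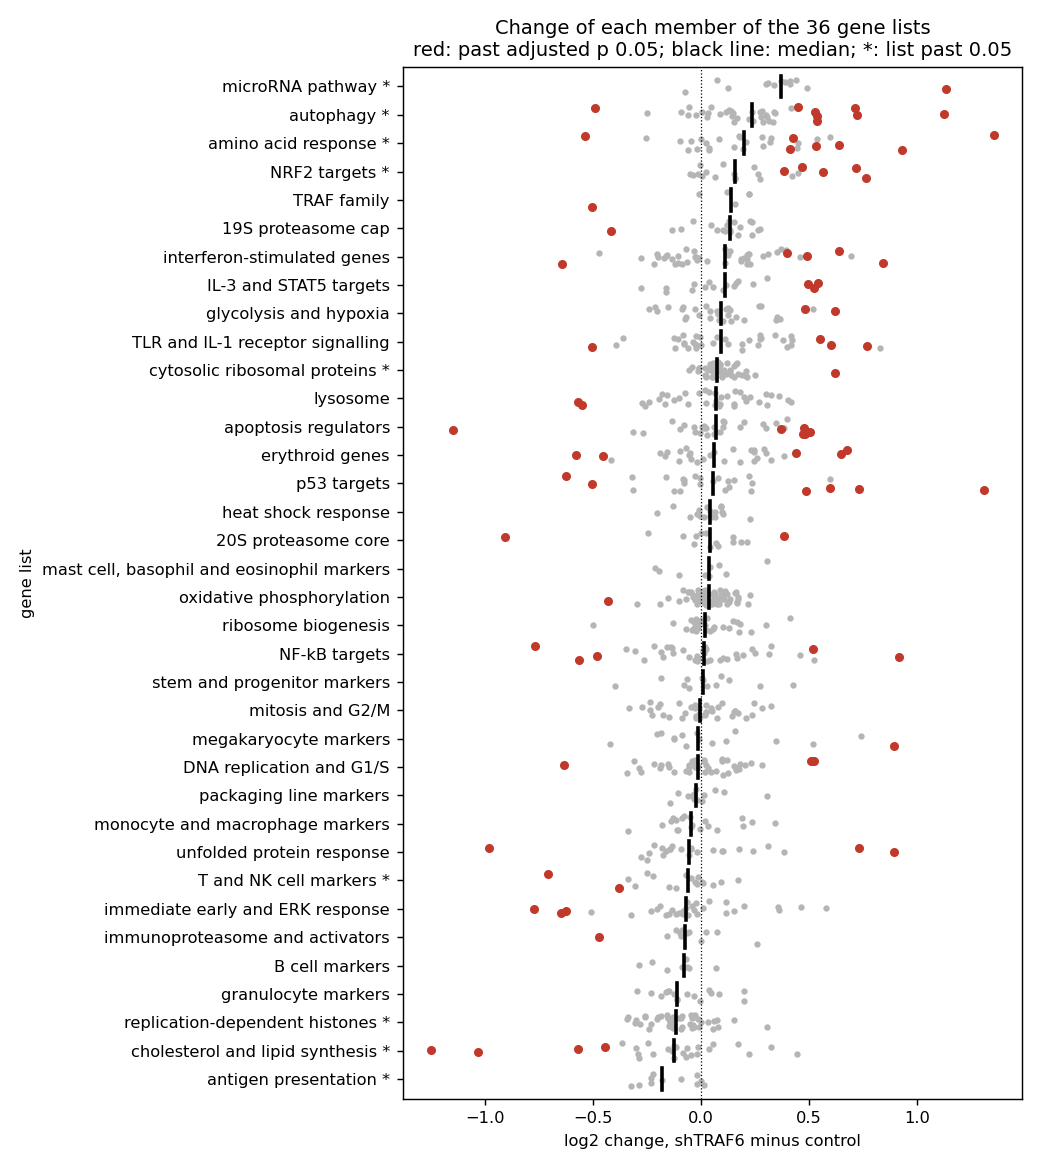
Log2 change (shTRAF6 minus control) of each measured member of the 36 gene lists, ordered by median (black lines), with members past an adjusted p of 0.05 in red and lists past camera's adjusted p of 0.05 starred. The medians run from -0.18 for antigen presentation to 0.37 for the microRNA pathway, and 9 lists are starred, 5 higher and 4 lower.

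In all, 9 of the 36 lists passed camera with the preset correlation, and 0 did with an estimated correlation (smallest adjusted p = 0.964, smallest unadjusted p = 0.121). The estimated correlations of these 9 lists ran from 0.016 (cytosolic ribosomal proteins) to 0.81 (microRNA pathway), above the preset 0.01. By fry, 0 passed for a change in one direction and 24 for a change in either.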

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

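Which probe sets to look at here was settled only after the fit had been run. In the fit over all 33297 probe sets, 5 of the 12083 with no listed gene were higher in shTRAF6 than in control, and 3 were lower. Their limma adjusted p-values lay close to the threshold, from 0.0297 to 0.0494. The largest rise was that of probe 7896565, from a mean log2 value of 6.84 to 8.04 (SE 0.094, limma adjusted p = 0.0466), and the largest fall that of probe 7894355, from 9.37 to 7.12 (log2 change -2.25, SE 0.13, limma adjusted p = 0.0369). Probe sets with no listed gene were noisier, with a 95th percentile of the replicate SD of 0.385 against 0.217 for those with 1 gene. What these probe sets measure was not analysed here, and no explanation was tested. The annotation used does not say whether they read transcripts or are controls of the array. No regulated transcript can therefore be read from them.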

How the results depend on the processing

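The fits over single probe sets, other than the planned count with every probe set, were chosen after the data had been seen. Replicate numbers are shared by both groups, but nothing says that they pair the samples, and the deviations of same-numbered arrays correlated at 0.158 over genes. The replicate block gave 1572 genes past the threshold in place of 906. The count was 1628 with quantile normalization, 2182 with centred arrays, 1457 with genes under the 50th percentile left out, 1872 with an eBayes trend, 1 without moderation, 27 with every probe set and 26 with its robust form. Leaving out 1 array gave 250 to 1099. With all arrays, 1203 genes passed with those under the 25th percentile left out, 861 with the brightest probe set and 839 in the robust fit. Testing 1-gene probe sets without averaging gave 824, so skipping the average alone does not account for the drop to 27. Without moderation 2 degrees of freedom remain by construction, and other causes of these differences were not tested. All 906 calls kept their direction with quantile normalization and centring, and leaving out an array could not change it, since their groups do not overlap. Genes at p under 0.05 and 1.5-fold numbered 362 to 671 with 1 array left out (421 with all), 880 with every probe set, 54 at 2-fold and 3066 at 1.2-fold.

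TRAF6 (log2 change -0.51) lost its call in the robust fit (adjusted p = 0.0508), without moderation (0.405), with every probe set (0.149, robust 0.153) and with single probe sets (0.0555), and with any array left out (-0.62 to -0.39). PSMA1 (-0.91) did so without moderation, with every probe set and with its robust form (0.0813), and ranged from -1.04 to -0.78 with 1 array left out. Lists past the threshold numbered 7 to 9 with 1 array left out, 0 with an estimated correlation, 0 by directional fry, 24 by mixed fry and 10 by the rank form of camera. Autophagy, the microRNA pathway, the amino acid response, NRF2 targets and lipid synthesis passed in every preset-correlation fit. Over the 9 lists, 87 of 99 preset-correlation alternatives kept the call, 12 lost it and 0 reversed, while each of the 9 lost it with an estimated correlation and by directional fry.

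For 175 other named genes, 1882 of 2238 alternatives stayed on the same side, 233 lost the call, 119 gained it and 4 changed sign, none of these called. With 1 array left out KRT8 ranged from -0.033 to 0.24, KRT19 from -0.39 to 0.096 (both changed sign without control 1) and CLC from -0.019 (without control 2; -0.013 without shTRAF6 2) to 0.25. Of 96 called ones, 40, 31, 8 and 51 lost the call without control 1, control 2, shTRAF6 1 and shTRAF6 2, all 96 without moderation, and 0 with the block. A lone array in a group was assumed to vary like the other group. Robust and unmoderated forms were not run for the gene lists, since camera sets its own moderation, and genes under a percentile have no value in that fit. Low signal limits dim probe sets, and the arrays give no detection value here.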

Other observations

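The tests of the 20S core, of falls with quantile normalization, of the share of falls among large changes, of snoRNAs by level, of the genes that contain snoRNAs and of other splits of the arrays were chosen after their results had been seen, as were the snoRNA class and the genes named in this part.

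Small nucleolar RNAs, which guide the modification of ribosomal and spliceosomal RNA, were higher in shTRAF6 cells. Of 175 measured, 28 rose and 0 fell by limma (16% called, against 4.81% of other genes; Fisher's exact test odds ratio 3.77, adjusted p = 2.65e-07 over 8 gene classes). Their median log2 change was 0.22 (95% bootstrap interval 0.18 to 0.26), with 161 above 0, and 0 of 10000 random lists matched on level had a median as high (highest 0.063). The interval, the Fisher test and the random lists take genes as independent. They measure spread over genes, not between samples, and so do the bootstrap intervals given below. With 1 array left out the median ran from 0.16 to 0.30. SNORA5A rose by 0.88, SNORA75 by 0.85 and SNORA6 by 0.85. The number of rises was 10 without control 1, 14 without control 2, 27 without shTRAF6 1 and 14 without shTRAF6 2. It was 52 with centred arrays or an eBayes trend, 40 with the replicate block, 33 with quantile normalization, 38 and 36 with genes under the 25th and 50th percentile left out (of 127 and 101 tested), 27 with the brightest probe set, 26 in the robust fit and 0 without moderation. Each of these fits had 0 falls.

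Some further genes outside the naming rule passed the test. The alpha-arrestins ARRDC3 and ARRDC4 rose by 1.14 and 1.13 and TXNIP, of the same family, by 0.56. PDK4, a relative of PDK1, rose by 0.98. While the calcineurin subunit PPP3CA fell by 1.55, its relative PPP3CB rose by 0.72 (adjusted p = 0.0216). TXNIP lost its call without control 1 (adjusted p = 0.0603), control 2 (0.0657) or shTRAF6 2 (0.0766), and PPP3CB without control 1 (0.0698) or shTRAF6 2 (0.0702).

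PSMA1 fell by 0.91. A shift of the proteasome genes as a group would lower the other 14 core subunits by about as much, and is argued against by their median log2 change of 0.054 (-0.25 to 0.38). A loss or silencing that lowers most genes around PSMA1 and TRAF6 is argued against by the 40 nearest measured genes. They had a median of 0.017 and quartiles of -0.13 and 0.14, 2 of them lower and 1 higher past the threshold. The 40 were taken without a filter on level, and genes that are not expressed could not fall. They also pool both loci, so a loss limited to a few genes at either is not excluded. An effect of TRAF6 on PSMA1 may explain the fall, as may action of the single hairpin on other transcripts, and these were not separated.

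Many genes fell by more than TRAF6 itself. With quantile normalization 183 called genes did so, and 184 as deposited, 174 of them in both. The count was lower without control 1, control 2 or shTRAF6 2, and higher without shTRAF6 1. TRAF6 is rescaled along with the other genes, so a shift between arrays largely cancels in this count. All called falls numbered 784 with quantile normalization and 277 as deposited. The count therefore cannot decide whether scaling between arrays plays a part. Falls made up 45.3% of called changes of at least 2-fold and 29.7% of smaller ones (Fisher's exact test odds ratio 1.96, 95% interval 1.07 to 3.57, p = 0.0208), but that excess depends on scaling, with an odds ratio of 1.42 (0.790 to 2.58, p = 0.263) with quantile normalization and 1.70 (0.943 to 3.04, p = 0.0609) with centred arrays. Action of the hairpin on other transcripts could give large falls, but matches to the hairpin were not searched, so it cannot be told apart from an effect of TRAF6 loss. A second hairpin was not analysed here.

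For the snoRNA rise, noise of dim probe sets is argued against by the random lists matched on level and by the 101 snoRNAs above the median level of all genes, whose median log2 change was 0.25 (95% bootstrap interval 0.21 to 0.31; all genes above that level 0.054). Higher RNA of the genes that hold the snoRNAs, as the whole cause, is argued against for the 19 called ones that lie within a measured gene (by position, strand not considered): those 19 genes had a median of 0.12 (0.053 to 0.19), under 0.25, which is 50% of the snoRNA median of 0.50, and 0 of them passed the test. The bound of 0.25 is raised because called snoRNAs were selected for their rise. Over all 82 measured snoRNAs with such a gene (median 0.30), the 64 genes had a median of 0.073 (0.051 to 0.13). That is under 0.15, 50% of the snoRNA median. Of the 64, 45 lay above 0, and 2 rose and 5 fell past the test. Several lay above 0.15, among them EPB41L4A (0.56), TNPO2 (0.45), CHD8 (0.44), SNHG17 (0.36) and SNHG29 (0.18). A difference in the recovery of short RNA may be involved. MiRNA genes had a median of 0.021, under 0.11, which is 50% of the snoRNA median. That bound was set after the snoRNA rise had been seen. The median level of miRNA genes (4.62) lies under the 25th percentile of all genes (5.68), too close to the floor for that bound to decide. The 20 snRNA genes, at a median level of 8.58, had a median of 0.091, and 2 rose and 0 fell. They are too few to decide it either. Recovery, a shift shared by this class on an array and an effect of TRAF6 loss thus cannot be told apart, transcription itself was not measured, and for the other called snoRNAs no containing gene was measured.

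The 4 arrays allow 3 splits into 2 and 2. Only 1, the real one, gave as many as 906 genes, and the highest of the others gave 0 (293 and 191 at an unadjusted p under 0.05). With 3 splits no share under 0.05 can be reached. Each of the other splits mixes the groups, so any difference between them, also a technical one, widens its residual spread. That pushes its count towards 0, so the contrast does not gauge chance.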
